A study of Homo sapiens with 6 samples.

How the data were processed

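Gene expression was measured in 6 cultures of HMLER cells, human mammary epithelial cells that were immortalised and transformed with an oncogenic Ras. Per the labels, 3 arrays came from cells infected with an empty retroviral vector and 3 from cells infected with the same kind of vector carrying FOXC2, a forkhead transcription factor. Cells were selected with blasticidin, and RNA was taken during exponential growth. Total RNA was converted to biotin-labelled cRNA, per the labels' protocols. The labels call the 3 arrays of each group biological replicates but do not say whether they came from separate infections, so the p-values measure the spread between these arrays.

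The deposited table holds log2 expression values for 54675 probe sets and 6 arrays. Per the submitters' processing notes the values were made with RMA, which corrects background, equalises the distribution of the arrays and summarises the probes of a set. Its version and the probe-set definition are not given in the sources used here. The log2 scale was read from the values, which run from 2.79 to 15.5. Array medians lie between 5.89 and 5.90, so a change that moved most transcripts in one direction would not be visible. The table carries no detection calls and no background estimate. A change against a group with low values therefore has no floor from which a bound could be computed, and fold changes of such genes should be read as differences on this scale. The number of arrays, 3 per group, limits the precision. The median SD between replicate arrays was 0.066 on the log2 scale for vector and 0.081 for FOXC2.

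Probe sets were named from the platform annotation supplied with the table. Of them, 41091 were listed with 1 gene symbol, 1801 with several, and 11721 had no symbol there. A further 62 control probe sets were left out of all gene tests. One probe set stood for each gene, the one with the highest mean over all 6 arrays, which gave 19775 genes. Of these, 19735 had an Entrez ID found in the GRCh38.p14 RefSeq gene table, and no symbol needed updating. 10523 genes had more than 1 probe set. No genome build belongs to the deposited table, so no coordinates are given. Only the chromosome and the order of neighbouring genes were taken from the gene table. Overlapping, antisense and paralogous transcripts can share probes, and no probe sequences were used here to separate them.

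The FOXC2 and vector arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate, no filter on low values). P-values were adjusted by the Benjamini-Hochberg method over all 19775 genes, with a threshold of 0.05. In all that follows, changes are FOXC2 minus vector on the log2 scale, with the standard error of the fit, and adjusted p-values of single genes come from this limma fit unless another is named. Gene lists were tested with camera (two-sided, preset correlation between genes of 0.01), with the correlation estimated from the data, and with fry. Their p-values were adjusted over 30 lists, 24 of pathways or gene groups and 6 of markers of other cell types. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The lists held 585 different genes, of which 43 had no probe set with a single name and were not analysed here. Older symbols were matched through the synonyms of the gene table.

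The lists, the alternatives and the rule for named genes were fixed before the data were examined. Named were 12 genes fixed in advance (FOXC2, PDGFRB, CDH1, EPCAM, CDH2, VIM, FN1, ZEB1, SNAI2, TWIST1, CD44 and CD24), the 8 largest rises and the 8 largest falls past the threshold whose groups did not overlap, and the 2 most changed members past the threshold of each pathway list. That gave 60 genes. Further members named as examples of a list, and the gene families and single genes of the additional observations, were chosen after their values were seen. List membership was not chosen on these arrays.

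The fit was tested on simulated arrays with the means and the spread of the real ones, with 200 of 19775 genes changed. Of genes simulated with log2 changes of 0.25, 0.5, 1 and 2 (50 each), it recovered 4%, 76%, 96% and 100%. Of its calls, 4.8% were unchanged genes. In the real comparison 7894 genes were called, so the Benjamini-Hochberg threshold was less strict there. These shares do not describe that comparison, in which a change of 0.21 in ANXA2 was called (limma adjusted p = 0.00751). In a second simulation a shift of 0.5 in the mesenchymal marker list was called, and 0 of the 27 lists that share no gene with it were.

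Alternatives were a replicate block, a second quantile normalization, median centring, a filter on dim probe sets, the mean of a gene's probe sets, each probe set on its own, a trended and robust variance model, array weights, no shrinkage of the variance, a floor of 5 on the log2 scale, an added 2-fold limit, and leaving out each array in turn. A run without the genes of chromosomes 4, 9 and 14 was added after seeing the data. Figures were drawn with matplotlib 3.10.9.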

Results

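The series compared HMLER cells carrying FOXC2 with HMLER cells carrying an empty vector, with 3 arrays in each group. Replicate arrays correlated across all probe sets with Pearson's r of 0.997 to 0.998, and arrays of different groups with r of 0.969 to 0.970. These correlations are across probe sets, which are not independent replicates.

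The comparison asks how the transcriptome of these cells differs when FOXC2 is introduced. FOXC2 itself was higher in the FOXC2 arrays in both of its probe sets. The brighter probe set measured 7.22 ± 0.11 in vector arrays and 11.92 ± 0.02 in FOXC2 arrays (mean log2 ± SD, n = 3 each), a change of 4.70 ± 0.066 (SE) or 26.1-fold, with a limma adjusted p of 1.84e-09. The other probe set measured 5.24 ± 0.14 and 7.93 ± 0.16, a change of 2.69 ± 0.101 (SE). In both, the 3 FOXC2 arrays lay above the 3 vector arrays. The sources used here do not say which part of the transcript each probe set covers or which part the vector carried, so introduced and endogenous FOXC2 are not separated here.

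Of 19775 genes, 7894 (39.9%) changed at an adjusted p under 0.05 by limma, 4013 higher and 3881 lower in FOXC2 arrays. Larger changes were more often falls. By at least 2-fold, 563 genes were higher and 855 lower, and by at least 10-fold, 75 were higher and 121 lower. The median change over all genes was 0.023. In 10005 genes the 3 arrays of one group all lay above the 3 of the other, against a share of 10% by chance. Of the changed genes, 637 had both group means below the median probe set. These calls rest on 1 probe set per gene. Of 10729 other probe sets of the changed genes, 4769 changed the same way, 262 changed the opposite way and 5698 did not pass. Among the control probe sets, those for ribosomal RNA averaged 10.54 ± 0.16 in vector and 11.22 ± 0.50 in FOXC2 arrays (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 arrays against 3 allow), a difference of 0.68 that was 0.42 without FOXC2 replicate 2.

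Among genes named by a probe set with a single symbol, the 8 largest rises were in COL3A1, UBE2QL1, COL6A1, GREM1, SRGN, PRRX1, IGFBP2 and RGS4. COL3A1, a fibrillar collagen chain, went from 4.98 ± 0.17 to 12.65 ± 0.01 (change 7.66 ± 0.085 SE). UBE2QL1, a relative of ubiquitin-conjugating enzymes, changed by 7.46 and COL6A1, a chain of type VI collagen, by 7.13. GREM1, a secreted antagonist of bone morphogenetic proteins, changed by 7.11. SRGN, the core protein of the proteoglycan serglycin, changed by 7.10, and PRRX1, a homeobox factor of mesenchyme, by 7.01. IGFBP2, which binds insulin-like growth factors, changed by 6.94, and RGS4, a regulator of G-protein signalling, by 6.90. Adjusted p-values of these 8 genes ran from 4.82e-10 to 1.59e-07. The ranking rests on 1 probe set per gene. With probe sets averaged, COL6A1 changed by 1.54, SRGN by 4.66 and COL3A1 by 4.89.

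The 8 largest falls among these genes were in KRT14, GJA1, PHACTR3, ANXA3, S100A14, CDH1, CSTA and ESRP1. Probe sets without a single symbol, not ranked with them, included falls of -9.45 and -7.40. KRT14, a keratin of basal epithelial cells, fell from 14.94 ± 0.03 to 6.03 ± 0.11 (change -8.90 ± 0.064 SE, 479-fold). GJA1, the gap junction protein connexin 43, changed by -7.92 and PHACTR3, a binder of protein phosphatase and actin, by -7.61. ANXA3, an annexin, changed by -7.35 and S100A14, a calcium-binding protein of epithelia, by -7.20. CSTA, a cystatin protease inhibitor of stratified epithelia, changed by -7.13. ESRP1, which directs epithelial splicing, changed by -6.86. Adjusted p-values of these 8 genes ran from 4.46e-10 to 4.45e-08.

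Genes of epithelial adhesion were lower in FOXC2 arrays. Of 24 measured epithelial adhesion and junction genes, 20 fell, 0 rose and 4 did not pass the test, with a median change of -2.37. CDH1, which encodes E-cadherin, went from 11.78 ± 0.03 to 4.59 ± 0.13, below the median of every array (change -7.19 ± 0.070 SE, 146-fold, adjusted p = 5.3e-10). EPCAM, an epithelial adhesion molecule, went from 11.73 ± 0.12 to 5.11 ± 0.28 (98.2-fold). The desmosomal gene DSP changed by -6.15 and the hemidesmosomal integrin ITGB4 by -3.42. The 4 members that did not pass were the claudins CLDN1 (0.03), CLDN4 (-0.05) and CLDN7 (-0.23), and TJP3. In vector arrays they stood at only 6.09, 6.36, 6.95 and 6.32, near the array medians of 5.89 to 5.90. They had less room to fall than the brighter members, so these values do not show that claudins were spared. The list was lower by camera (adjusted p = 4.48e-15) and was called too with an estimated correlation (adjusted p = 0.0236). Adjusted over the list alone, 20 members fell as well. The change of CDH1 was -3.81 when its 2 probe sets were averaged; the other probe set measured 4.78 in vector and 4.36 in FOXC2 arrays.

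A list fixed as epithelial transcription and splicing regulators also held other epithelial genes. Of its 19 measured members, 15 fell and 0 rose (16 fell adjusted over the list alone), with a median change of -2.71. Of the 10 transcription or splicing factors, 6 fell, among them ESRP1, OVOL2 (-3.50) and GRHL2 (-2.29), and the transcription factors ELF3, EHF, OVOL1 and ELF5 did not pass. In vector arrays those that did not pass were already dim, at 6.7, 5.57, 6.62 and 4.68, although GRHL1 at 6.51 changed by -1.09. The other 9 members all fell: RAB25, a small GTPase of epithelial trafficking (-6.44, 86.7-fold), the membrane serine proteases ST14 and PRSS8, their inhibitors SPINT1 and SPINT2, and AP1M2, MAL2, TMEM30B and CDS1, which act in membrane traffic or lipid metabolism. The list was lower by camera (adjusted p = 3.15e-11; adjusted p = 0.0342 with an estimated correlation). This list and the adhesion list were the only 2 of 30 called under both settings of camera.

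Among keratins and differentiation genes, falls outnumbered rises. Of 12 measured keratins, 5 fell, 2 rose and 5 did not pass (6 fell and 2 rose adjusted over the list alone). Of those that did not pass, KRT7 was bright in vector (13.74) and FOXC2 arrays (13.55). KRT4, KRT13, KRT19 and KRT23 were dim already in vector arrays, at 4.21 to 5.42. KRT6A, KRT6B, KRT17 and KRT81 of this list had no probe set with a single name and were not analysed as genes. The counts and the list test leave them out and do not show whether these keratins changed. KRT5, the basal partner of KRT14, changed by -6.77 (109-fold), and KRT18, a keratin of simple epithelia, by -1.05, while KRT8, which pairs with KRT18, rose by 0.60. Camera called the keratins lower with an adjusted p of 0.0106, and the call was lost with an estimated correlation (adjusted p = 0.324). Of 24 epidermal differentiation genes, 12 fell, 1 rose and 11 did not pass (13 and 1 adjusted over the list alone). CSTA and SPRR1B, a component of the cornified envelope (-3.11), changed most. That list had a camera adjusted p of 0.000381, against an adjusted p of 0.0905 with an estimated correlation.

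**Figure D1:**
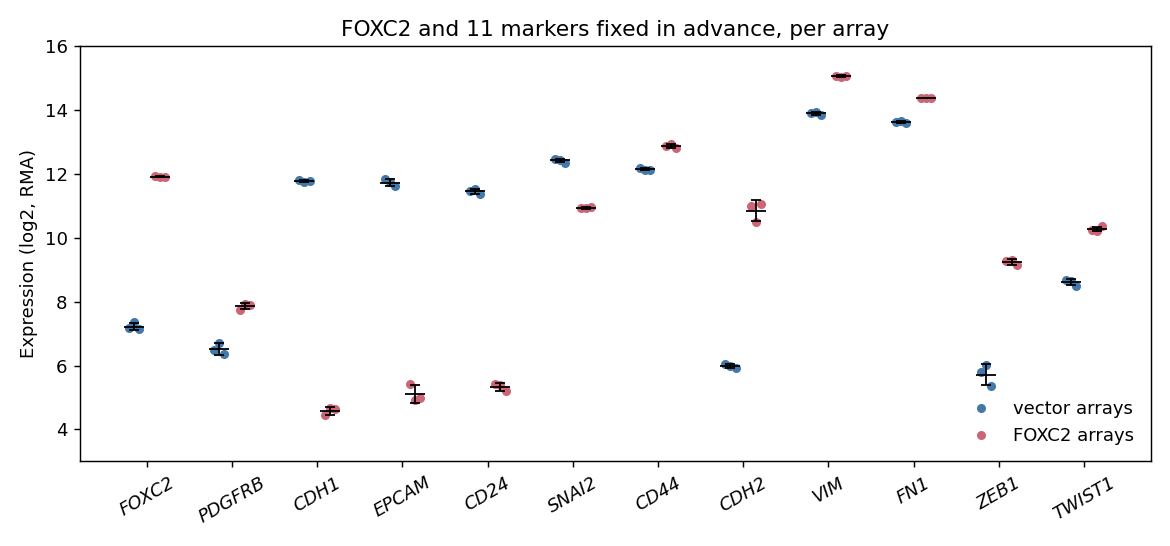
Expression (log2, RMA) of FOXC2 and 11 markers fixed in advance, with a point for each array, vector in blue and FOXC2 in red, and a black line and bar for the mean ± SD of 3 arrays. The groups do not overlap for any of the 12 genes; CDH1, EPCAM and CD24 lie between 11.46 and 11.78 on average in vector arrays and between 4.59 and 5.33 in FOXC2 arrays.

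Mesenchymal markers were higher in FOXC2 arrays for most measured members. Of 30, 18 rose, 3 fell and 9 did not pass the test (19 rose and 3 fell adjusted over the list alone), with a median change of 0.69. CDH2, which encodes N-cadherin, went from 5.99 ± 0.06 to 10.86 ± 0.32 (change 4.87 ± 0.142 SE, 29.2-fold). FBN1, the microfibril protein fibrillin, changed by 4.52. VIM, the intermediate filament vimentin, was already high in vector arrays at 13.90 ± 0.04 and reached 15.06 ± 0.03 (2.23-fold). FN1, fibronectin, went from 13.63 to 14.37 (1.67-fold). The 3 members that fell were CDH11 (-4.26), another mesenchymal cadherin, PDPN (-2.41), the membrane glycoprotein podoplanin, and CALD1. The smooth muscle genes TAGLN (0.09) and CNN1 (0.02) and the matricellular gene POSTN (0.01) did not pass. Camera gave an adjusted p of 0.000209, and the call was lost with an estimated correlation (adjusted p = 0.243).

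Most measured genes of the extracellular matrix were higher in FOXC2 arrays. Of 27 measured structural genes, 17 rose and 6 fell, over all genes and over the list alone alike. COL3A1 and COL6A1 changed most. COL6A2 rose by 6.37, COL1A1 by 5.26 and the elastic-fibre gene FBLN5 by 5.41. COL1A2, whose product joins that of COL1A1 in type I collagen, stood at 5.53 in vector and 5.59 in FOXC2 arrays and did not pass (adjusted p = 0.713). Its other probe sets differed by 0.18 and 0.31. Of the 5 probe sets of COL1A1, 3 differed by 5.08 to 5.96 and the others by 0.02 and 0.05. LAMB3, an epithelial laminin chain, changed by -3.38 and TGFBI, a secreted adhesion protein, by -3.44. The list was higher by camera (adjusted p = 0.000381), a call lost with an estimated correlation (adjusted p = 0.0905). Averaging a gene's probe sets reduced the change of COL6A1 to 1.54 and of COL3A1 to 4.89. Markers of adult fibroblasts, 9 of 11 of which also stand in another list, moved with the matrix and mesenchymal lists. Of the 11, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.00254, and an adjusted p of 0.131 with an estimated correlation. Of those fibroblast markers, DCN rose by 4.11 and FAP by 1.01. LUM (0.17), DPT (0.14) and SFRP2 (0.07) did not pass, and MFAP5 fell by 1.16.

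Matrix proteases and their inhibitors changed in both directions, with 12 of 26 higher and 6 lower (14 and 6 adjusted over the list alone; camera adjusted p = 0.125). MMP1, interstitial collagenase, went from 4.88 ± 0.13 to 11.74 ± 0.10 (116-fold). SERPINE2, a secreted serine protease inhibitor, changed by 2.98, and averaging its probe sets gave 1.85. PLAU, urokinase, changed by -1.76.

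Transcription factors of the epithelial-mesenchymal transition did not move together. Of 16 measured, 6 rose, 6 fell and 4 did not pass (8 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.806). PRRX1, ZEB1 (3.53, 11.5-fold), ZEB2 (3.21), TBX3 (1.88), TWIST1 (1.67, 3.18-fold) and HMGA2 (0.62) rose. The other probe sets of ZEB1 rose by 2.09 to 6.86. SNAI2, the transcription factor Slug, fell from 12.42 ± 0.06 to 10.94 ± 0.02 (2.79-fold, adjusted p = 2.06e-07). TCF4 changed by -3.17, KLF8 by -1.75, SOX4 by -1.68, ETS1 by -1.03 and TWIST2 by -0.23. SNAI1 (0.26), GSC (0.14) and FOXQ1 (0.02) did not pass.

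The stem and progenitor list was likewise split, with 3 of 22 higher and 7 lower over all genes and over the list alone (camera adjusted p = 0.5). CD24, a surface glycoprotein that is low in mammary cells with stem-like properties, went from 11.46 ± 0.07 to 5.33 ± 0.12 (69.9-fold). CD44, a hyaluronan receptor that is high in such cells, went from 12.16 ± 0.04 to 12.88 ± 0.06 (1.65-fold, adjusted p = 1.62e-05). The probe sets of CD44 disagreed: beside the one used, 2 fell (the larger fall was -1.01), 4 rose past the threshold, and the mean over all probe sets changed by only 0.15. ITGA6, a laminin-binding integrin, changed by -1.90 and the aldehyde dehydrogenase ALDH1A3 by -1.70. DNER rose by 1.85 and SOX9 by 1.27. PROM1 (-0.05) and ALDH1A1 (0.30) did not pass.

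The receptor for platelet-derived growth factor, PDGFRB, was higher in FOXC2 arrays. It went from 6.52 ± 0.18 to 7.86 ± 0.10, a change of 1.35 with a 95% confidence interval of 1.12 to 1.57 (2.55-fold, adjusted p = 1.29e-05). Of 12 genes of the PDGF pathway, 5 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.217). PDGFRL, a receptor-like relative, changed by 4.01, the co-receptor NRP1 by 2.59 and the ligand gene PDGFC by 1.31, while the ligand gene PDGFA changed by -1.42. PDGFRA rose by 0.44. With its probe sets averaged, NRP1 changed by 1.25.

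Other receptor tyrosine kinases went both ways, with 4 of 22 higher and 9 lower (5 and 9 adjusted over the list alone; camera adjusted p = 0.222). FGFR3 changed by -6.55 (-3.31 with its probe sets averaged), ERBB3 by -4.04 and MST1R by -3.40. ROR1, a Wnt-binding receptor, changed by 5.25 (38-fold) and FGFR1 by 2.91. In the main setting camera called no list of lineage markers of the mammary gland. Of 17 basal and myoepithelial markers, 8 fell and 4 rose, over all genes and over the list alone (camera adjusted p = 0.0877). With probe sets averaged, camera called this list (adjusted p = 0.0184). The falls included KRT14 (-8.9), KRT5 (-6.77) and CDH3 (-5.33), and the rises MME (3.21) and MYLK (2.91). Of 19 luminal markers, 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.5), the falls being KRT18 and GATA3, a luminal transcription factor (-1.23).

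**Figure D2:**
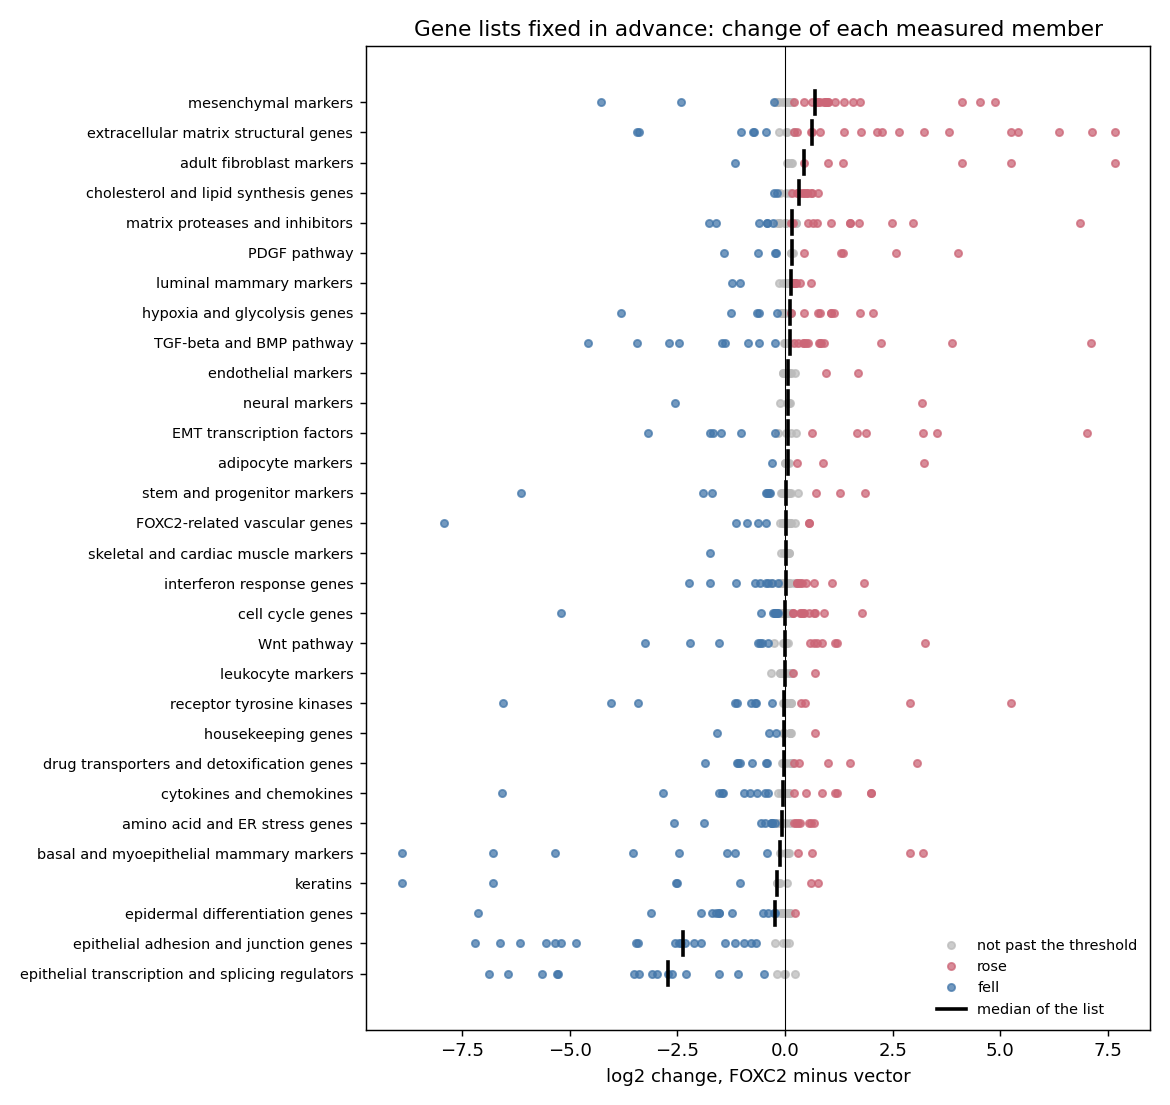
Change of each measured member of the 30 gene lists fixed in advance (log2, FOXC2 minus vector); each point is a gene, red where it rose, blue where it fell and grey where it did not pass the threshold, and the black bar is the median of the list. The medians of the 2 epithelial lists lie at -2.37 and -2.71, while those of the other 28 lists lie between -0.24 and 0.69.

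Signalling lists held strong changes of single genes and were not called by camera. Of 27 genes of the TGF-beta and BMP pathway, 13 rose and 9 fell, over all genes and over the list alone (camera adjusted p = 0.691). GREM1 and the latent TGF-beta binding protein gene LTBP1 (3.89) rose, and FST, the activin antagonist follistatin (-4.56), and ID3 (-2.69) fell. Of 21 Wnt genes, 7 rose and 7 fell, over all genes and over the list alone (camera adjusted p = 0.806), with WNT5B at 3.25 and the antagonist SFRP1 at -3.24. With probe sets averaged these were 1.44 and -1.82. Of 24 vascular genes chosen for their relation to FOXC2, 2 rose, 5 fell and 17 did not pass, with 2 and 5 over the list alone (camera adjusted p = 0.689). GJA1 and NOTCH1 (-1.13) changed most, and CXCR4 (0.03), ANGPT2 (0.12), DLL4 (0.06) and HEY2 (0.24) did not pass. Of 25 cytokines and chemokines, 10 fell and 7 rose, over all genes and over the list alone (camera adjusted p = 0.301). IL1A, interleukin 1 alpha, changed by -6.56 (-3.34 with probe sets averaged) and PTGS2, cyclooxygenase 2, by -2.84, while CXCL1 and LIF rose by 2.00 and 2.01.

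Of 30 cell cycle genes, 11 rose and 8 fell (12 and 10 adjusted over the list alone; camera adjusted p = 0.806). CCND2, cyclin D2, changed by -5.20 (-2.84 with probe sets averaged), the inhibitor gene CDKN2B by 1.78, and the proliferation marker MKI67 by -0.56. Of 16 genes of cholesterol and lipid synthesis, 11 rose and 2 fell, over all genes and over the list alone, led by INSIG1 (0.77) and DHCR7 (0.62). That list had a camera adjusted p of 0.0106, and an adjusted p of 0.362 with an estimated correlation. In the hypoxia and glycolysis list 9 of 23 rose and 5 fell (13 and 5 over the list alone; camera adjusted p = 0.281), with ENO2 at 2.05 and NDRG1 at -3.80. In the amino acid and ER stress list 7 of 20 rose and 8 fell (8 and 8 over the list alone; camera adjusted p = 0.689), the largest changes being falls of the transporter genes SLC7A5 (-2.58) and SLC7A11 (-1.88). In the interferon list 8 of 27 rose and 9 fell (11 and 10 over the list alone; camera adjusted p = 0.806), with PSMB9 at 1.84 and IFIH1 at -2.22. In the drug transporter and detoxification list 5 of 20 rose and 7 fell, over all genes and over the list alone (camera adjusted p = 0.689), with CYP1B1 at 3.07 and GCLC at -1.86. Of 11 housekeeping genes, 1 rose and 3 fell (2 and 3 over the list alone; camera adjusted p = 0.859), with GUSB at 0.70 and TFRC at -1.58. ACTB (-0.04) and GAPDH (0.13) did not pass.

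Camera called none of the lists of markers of other cell types, apart from fibroblasts. Of 13 leukocyte markers 2 rose (1 over the list alone), of 10 endothelial markers 2 rose, of 8 adipocyte markers 3 rose and 1 fell, of 8 muscle markers 1 fell, and of 8 neural markers 1 rose and 1 fell. For the last 4 lists the counts over the list alone were the same. Camera adjusted p-values of the 5 lists ran from 0.281 to 0.806. Fry, which does not compare a list with other genes, called the adipocyte (adjusted p = 8.85e-05), endothelial (0.000356) and neural lists (0.0231) as higher and the muscle list (0.00158) as lower, and did not call the leukocyte list (0.13). Single members changed, among them PPARG (3.23), NEFL (3.19), ROBO4 (1.69), PECAM1 (0.96) and CD14 (0.69). As a sign of RNA quality, the 5′ less 3′ difference of the ACTB control probe sets was -0.22 ± 0.08 in vector and -0.44 ± 0.18 in FOXC2 arrays (SD, n = 3; exact two-sided permutation p = 0.2). That test cannot go below 0.1 with 3 arrays against 3. For GAPDH the difference was -0.05 ± 0.02 and -0.07 ± 0.05 (exact permutation p = 0.8, n = 3).

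The median, mean and test of a list differed in sign for the stem and progenitor, vascular, cell cycle, muscle, interferon and Wnt lists, none of which camera called. Averaging probe sets also moved FN1 to 1.21, FBN1 to 2.88, SRGN to 4.66, CDKN2B to 1.18, GUSB to 0.38, NOTCH1 to -0.53, TFRC to -0.71, GATA3 to -0.72 and IFIH1 to -0.76. All 60 named genes kept their direction and their side of the threshold under every alternative in which they were tested. These included the run without each array in turn, but not the 2-fold limit or each probe set on its own.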

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

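The tests of cell mixing, RNA degradation and probe set choice were chosen after the values they bear on had been seen; the prediction on other splits of the arrays was written before.

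Some signal lay in probe sets that the comparison of named genes did not use. These were 13524 probe sets, 1801 with several symbols, 11721 with none and 2 whose symbol belonged to 2 Entrez IDs. Of them, limma called 801 higher and 796 lower in FOXC2 arrays, with 127 and 185 of them changed by at least 2-fold. The largest fall there, -9.45, exceeded that of KRT14 (-8.90). The control probe sets for ribosomal RNA were also higher in FOXC2 arrays, by 0.68 on the log2 scale. They averaged 10.54 ± 0.16 in vector and 11.22 ± 0.50 in FOXC2 arrays (SD, n = 3; exact permutation p = 0.1, the smallest this design allows). Without FOXC2 replicate 2, which was highest at 11.73, the difference was 0.42, and FOXC2 replicate 1 at 10.73 lay close to the highest vector array at 10.70. The hybridisation spikes differed by 0.06.

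With epithelial lists lower and matrix genes higher, stromal fibroblasts mixed into the FOXC2 cultures would bring their abundant transcripts, yet COL1A2 changed by at most 0.31 in any of its 3 probe sets and stood at 5.59 in FOXC2 arrays, while COL3A1 and COL1A1 rose by 7.66 and 5.26. This argues against fibroblasts that express COL1A2, although DCN (4.11), PDGFRB (1.35) and FAP (1.01) of the same marker list rose. For leukocytes, endothelium, fat, muscle and nerve, the median change plus the SD of a marker list's members was at most 1.62. The median change of the epithelial adhesion list was -2.37. This comparison cannot decide the question, because a rise of markers and a dilution of epithelial transcripts are not on the same scale. Cells that lack epithelial transcripts would dilute them all alike. Yet KRT14 and KRT5 changed by -8.9 and -6.77, and KRT18 and KRT7, similarly bright in vector arrays, by -1.05 and -0.19. These values argue against dilution by such cells as the whole source of the epithelial falls. A smaller share is not excluded, since PPARG (3.23), NEFL (3.19) and ROBO4 (1.69) rose and fry called the adipocyte, neural and endothelial lists higher. For a difference in RNA degradation, a shift of over 1 in the 5′ less 3′ difference of ACTB was required, but it moved by -0.22 (SD 0.18 in FOXC2 arrays) and that of GAPDH by -0.02, and loss of RNA in FOXC2 arrays would not raise COL3A1 by 7.66; this argues against degradation as the source of the pattern, although a small difference is not excluded. The effect of the introduced FOXC2, and selection of mesenchymal cells during infection and drug treatment, stay open.

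CDH11 and PDPN fell in the mesenchymal list, where 18 of 30 members rose. SNAI2 and TCF4 were among 6 falls in the list of epithelial-mesenchymal transition factors, where 6 rose. The choice of probe set does not account for the falls of TCF4, CDH11 and PDPN. Of 13 other probe sets of the 4 genes, 12 passed the threshold and 12, or 100%, fell; SNAI2 has no other probe set. No biological explanation was tested.

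The count of 7894 genes was set against other splits of the arrays. In 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, limma called that many. The highest count in the other splits was 0, with 231 to 354 genes at an unadjusted p under 0.05 against 9152 in the real split. With 10 splits, a share under 0.05 cannot be reached. Each of the other splits also puts arrays of both groups on each side, so the difference between the groups enters the spread. Their count of 0 was therefore nearly certain beforehand and does not measure chance.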

How the results depend on the processing

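The count of 7894 changed genes stayed between 6801 and 7480 when 1 array was left out, between 6956 and 8340 under the other settings of the fit, and at 6835 without the genes of chromosomes 4, 9 and 14, an alternative chosen after seeing the data. It was 1418 (563 higher, 855 lower) when a 2-fold change was also required, by construction, and 13990 probe sets (7177 and 6813) when each was tested on its own, since more features were tested. With the replicate block it was 7293. The replicate numbers do not pair the arrays: deviations of same-numbered arrays from their group means correlated at -0.084 to -0.001, and no array correlated best with its own number. The block changed no call of a list or a named gene. Of the 60 named genes, 20 moved by over 1.5 times when probe sets were averaged. Under the other alternatives in which they were tested 0 did, and 0 changed direction or call under any tested. The 2-fold limit and each probe set on its own were not among these. Named genes such as FN1 (0.74) changed by under 2-fold, and a probe set of CD44 changed by -1.01. A second quantile normalization gave a share of lower calls of 46.4%, against 49.2%. With an estimated correlation, 6 of 8 called lists were lost, at adjusted p of 0.243 (mesenchymal), 0.0905 (matrix), 0.0905 (epidermal differentiation), 0.324 (keratins), 0.362 (cholesterol) and 0.131 (fibroblast markers). The basal markers were called at 0.0184 with probe sets averaged, and the cytokines at 0.0458 without chromosomes 4, 9 and 14. Fry, which asks a different question, called lists that camera did not: cell cycle (0.00158) and TGF-beta and BMP (0.00158) as lower, where camera's direction was higher; and in camera's direction adipocyte (8.85e-05), ER stress (0.00118), basal (4.62e-06), cytokine (0.000335), drug transporter (0.0295), EMT factor (0.00659), endothelial (0.000356), vascular (8.8e-05), interferon (0.0218), protease (4.75e-06), neural (0.0231), PDGF (6.34e-06), receptor kinase (0.00158), muscle (0.00158) and stem lists (1.31e-05). The estimated correlation was below the preset 0.01 for the matrix (-0.021), epidermal differentiation (0.002) and fibroblast lists (-0.052). A higher correlation between genes therefore does not account for the loss of these calls. The estimate was also below the preset for the epithelial adhesion list (-0.031), whose camera adjusted p rose from 4.48e-15 to 0.0236. The settings of camera thus differ by more than the correlation between genes, and a lost call does not by itself show sensitivity to that correlation. The estimate was 0.068 for the mesenchymal, 0.101 for the keratin and 0.111 for the cholesterol list. The cause of the lost and gained calls was not tested further. No detection call exists in the table, so how far dim genes lie above background is unknown.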

Other observations

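The tests of gene families, and the single genes named with them, were chosen after the results were seen; the tests on chromosomes were fixed before they were run, for a pattern noticed in the same data.

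Among gene families read from symbols, the IGF-binding proteins stood out. Of 7 measured members, 5 rose and 0 fell, with a median change of 2.72: IGFBP2 by 6.94, IGFBP4 by 4.09, IGFBP3 by 4.04, IGFBP6 by 2.72 and IGFBP7 by 1.71. Camera gave an adjusted p of 0.000205 over 12 families, and an adjusted p of 0.137 with an estimated correlation. Of 28 HOX genes, 12 rose and 1 fell, HOXB6 by 1.85, HOXC6 by 0.98 and the other 10 by less (camera adjusted p = 0.0266; adjusted p = 0.196 with an estimated correlation). Of 13 connexins, 4 fell and 1 rose (camera adjusted p = 0.0465; adjusted p = 0.203 with an estimated correlation), and of 21 ephrins and Eph receptors, 10 fell and 3 rose (camera adjusted p = 0.0465; adjusted p = 0.203 with an estimated correlation). Of 43 collagens, 14 rose and 7 fell (camera adjusted p = 0.0465; adjusted p = 0.292 with an estimated correlation). The medians of these 5 families kept their sign under median centring and a second quantile normalization. Transcription factors with low vector values included NR2F1, an orphan nuclear receptor, which went from 4.50 ± 0.15 to 11.16 ± 0.05, EBF2 (3.86 ± 0.02 to 9.93 ± 0.14) and EBF1 (4.03 ± 0.48 to 9.97 ± 0.02). APOBEC3B, a DNA cytidine deaminase, went from 6.16 ± 0.11 to 10.71 ± 0.12 (SD, n = 3).

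Genes on 3 chromosomes were shifted in their median. Over genes above the median probe set, the median change was -0.201 on chromosome 4 (436 genes, 51.4% fell), -0.173 on chromosome 9 (533 genes, 49.5% fell) and 0.224 on chromosome 14 (430 genes, 52.1% rose), against -0.05 to 0.075 on the other 20 chromosomes. The median of the chromosome's genes in each FOXC2 array, relative to the vector mean and less the same median over all these genes, was -0.221 ± 0.033, -0.190 ± 0.008 and 0.219 ± 0.023 (SD, n = 3). Camera gave an adjusted p of 2.59e-05 for each, but 0.844, 0.196 and 0.196 with an estimated correlation. A few strongly changed genes do not account for it, since without genes changed by over 1 the smallest of the 3 medians was still 0.145 in size. Against expression level or normalization, 0% of 10000 random gene sets matched on mean expression had a median as far from that of all 12889 genes above the median probe set as any of the 3, although the same held for chromosome 19. A candidate explanation is a different number of copies of these chromosomes in the 2 cell populations: at least 9 of 10 runs of neighbouring genes on each had a median in the chromosome's direction, and medians on chromosomes 9 and 14 reached -0.568 and 0.581 in single runs. Chromosomes 19 and 20 also had 10 of 10 runs in 1 direction, at far smaller medians of 0.075 and 0.070, so the test of runs is not specific, and GC content, not tested here, stays open.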
